A study of Mus musculus with 18 samples.

How the data were processed

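RNA sequencing had been performed on 18 libraries of T23 cells, a mouse prostate adenocarcinoma line, in 6 groups of 3 replicates. The groups were T23 cells alone, with wild-type fibroblasts, with Sparc-deficient fibroblasts, with enzalutamide (an androgen receptor antagonist), with fibroblasts and enzalutamide, and with fibroblasts, enzalutamide and isoliquiritigenin (a plant chalcone). Per the labels, total RNA went into stranded libraries made after capture of polyadenylated RNA, with dUTP in the second strand, and the libraries were run on a NextSeq 550.

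The deposited files hold raw counts per gene, one file per library, with Ensembl identifiers and no normalisation. Whole numbers from 0, with library totals that differ, were found in each of the 18 files. Per the labels, the authors used bcl2fastq 2.20.0.422, FastQC 0.11.9, cutadapt 2.9, STAR 2.6.1d, featureCounts 2.0 and DESeq2 (no version given), with the mouse genome build GRCm38. The annotation release, the strand setting of the counting and the treatment of reads that match several places are not stated in the sources used. Counts of overlapping or antisense genes, and of genes with close paralogs or pseudogenes such as H2-Q7, Oas1a, Ifi205 and Eno1, are therefore uncertain. Each file lists 55487 genes, of which 55141 were paired with a symbol through GENCODE M21. The 346 without a symbol held 0.0297% of all counts. Coordinates are those of GENCODE M21 on GRCm38.

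Library totals ranged from 16.1 to 26.7 M counts, with 18123 to 20154 genes detected. A count of 0 in a library allows up to 3 counts, which is 0.112 to 0.186 CPM (counts per M counts of the library) at these totals. Intervals for shares of single libraries are 95% Wilson intervals. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Replicates spread more than counting error alone would give. The ratio of chi-square to its degrees of freedom between replicates was 2.55 to 12.7, apart from the pairs that include replicate 2 of enzalutamide without fibroblasts, where it was 586 and 595. The labels do not say whether replicates are separate cultures. Replicate numbers did not pair libraries across groups. None of the 15 pairs of groups had same-number correlations above 0.1 throughout, and these correlations ran from -0.144 to 0.0982.

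Genes with enough counts were kept with the edgeR function filterByExpr (minimum count 10), which left 13600 genes. Counts were scaled by TMM and fitted in edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with a quasi-likelihood model that held all 18 libraries and a mean per group, with 12 residual degrees of freedom and a biological coefficient of variation of 7.03%. Each comparison is a two-sided quasi-likelihood F test of a contrast of group means. Adjusted p are Benjamini-Hochberg values over the 13600 genes of that comparison, and a gene is called when its adjusted p is under 0.05. Log2 fold changes are given ± SE, computed as the size of the log2 fold change over the square root of F, and normalised CPM as mean ± SD over 3 libraries. A single simulated data set with the spread of these data held 12044 of the 13600 genes, without those of lowest count. There the test called 79% of the genes changed 1.5-fold and 95% of those changed 2-fold, and 7 of 11820 unchanged genes. These shares do not cover the genes left out.

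The design has 7 comparisons of 3 libraries against 3 and 1 interaction, which tests whether the enzalutamide response differs with and without fibroblasts. The comparisons, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except the alternatives and tests named as added later. The rule names, in each comparison, Sparc, Hspa5, Il6, Syp, Chga, Eno2 and Ncam1 whatever their values. It adds the 5 called genes with the largest positive and the 5 with the largest negative log2 fold change among those with a symbol, a mean of at least 5 CPM and no overlap between the ranges of both groups (for the interaction, no range condition). It further names up to 3 called members, by smallest p, of each gene list past its test. Members of lists named outside this rule were chosen after their values were seen, as were Stmn2, Uchl1, Syt1, Cplx2, Col1a1, Vim, Epcam, Krt8, Krt18 and Insm1. A few genes the rule names are not reported here, and no others were named in their place.

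Of 24 gene lists, 23 had tested members. They were compared with all other tested genes by camera (limma) with a preset inter-gene correlation of 0.01 and adjusted over the 23 lists of each comparison. The same test was run with the correlation estimated for each list. That test is reported as an adjusted p with an estimated correlation. Counts of called members are given over all genes and adjusted over the list alone. Lists came from textbook knowledge, not from these libraries. Of the 30 fibroblast markers, 25 stand at 10 CPM or more in T23 cells alone, so the list does not tell fibroblasts from T23 cells. Older symbols Ctgf and Cyr61 were read as Ccn2 and Ccn1.

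The alternatives were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, the replicate number as a block, only the compared groups in the fit, and each library left out in turn. Chosen after the data had been seen were a fit without replicate 2 of enzalutamide without fibroblasts for every comparison, a term for the numbering series of the titles, and a fit on protein-coding nuclear genes only. Gene lists were tested again only with RLE, the replicate block, the numbering term, an estimated correlation and without that replicate 2. Overlaps between responses were compared with the product of the list sizes over the number of tested genes, per direction. For the pair that shares control libraries, correlations were compared with those in 40 simulated data sets with unchanged groups. Other splits of the libraries were counted for each comparison (10 each, and 100 seeded regroupings for the interaction). Lists of Wnt and LXR targets were added after Axin2 and Abca1 had been seen, and their members named in the observations were chosen after their values were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No library was left out of the comparisons as reported, and isoform use and sequence variants were not examined.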

Results

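The data are gene counts from 18 poly(A) RNA-seq libraries of T23 mouse prostate adenocarcinoma cells, with 3 replicates in each of 6 groups. T23 cells had been grown alone, with wild-type fibroblasts, or with Sparc-deficient fibroblasts, and further groups received enzalutamide, enzalutamide with fibroblasts, or enzalutamide with fibroblasts and isoliquiritigenin. The series title concerns a fall of SPARC in stroma cells on castration and neuroendocrine differentiation of prostate cancer, so the comparisons ask what fibroblasts, their Sparc and androgen receptor blockade do to the tumour cell transcriptome. Sample descriptions of both enzalutamide co-culture groups speak of human fibroblasts, whereas their titles carry the same fibroblast name as the wild-type co-culture. Species and line of those fibroblasts therefore stay open, and comparisons between treated and untreated co-cultures assume the same fibroblasts. The index that ends each title restarts at 1 after index 16 (the titles skip some numbers), so that replicates 2 and 3 of the enzalutamide co-culture and all isoliquiritigenin replicates form a second numbering series.

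Library totals averaged 20.8 M counts ± 1.42 (SD, n = 3) in T23 cells alone, 20.9 ± 3.40 with wild-type fibroblasts and 21.5 ± 1.23 with Sparc-deficient fibroblasts. The averages were 20.2 M ± 3.52 with enzalutamide, 20.4 ± 0.537 with enzalutamide and fibroblasts, and 23.6 ± 2.92 with isoliquiritigenin added (n = 3 each). In replicate 2 of enzalutamide without fibroblasts, 26.4% of the counts (95% Wilson interval 26.4 to 26.5%) fell on CT010467.1 (ENSMUSG00000106106), an annotated ribosomal RNA gene on chromosome 17 from 39846353 to 39848827. That library held 11.8 M counts without the gene. Genes of the mitochondrial genome took 0.924% ± 0.161 of the counts in T23 cells alone, 1.02% ± 0.282 with wild-type and 1.42% ± 0.412 with Sparc-deficient fibroblasts (SD, n = 3). Their share was 2.74% ± 1.16 with enzalutamide, 2.32% ± 0.667 with enzalutamide and fibroblasts and 3.42% ± 0.536 with isoliquiritigenin added.

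**Figure D1:**
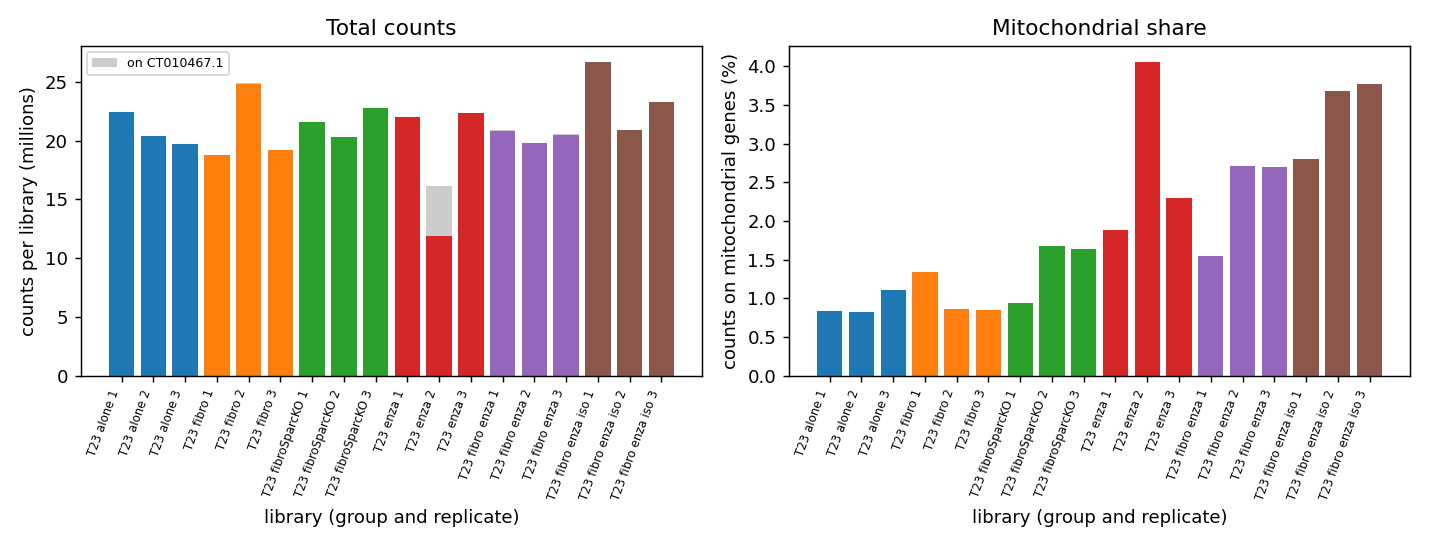
Left, counts per library in M, with counts on the ribosomal RNA gene CT010467.1 in grey; right, the percentage of counts on mitochondrial genes per library. Bars are single libraries coloured by group, and replicate 2 of enzalutamide without fibroblasts has 26.4% of its counts on CT010467.1 and 4.06% on mitochondrial genes.

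T23 cells expressed mesenchymal genes at high levels in every group. Alone, they had 10790 CPM ± 131 (SD, n = 3) of Col1a1, a chain of type I collagen, and 4012 CPM ± 71.1 of the intermediate filament gene Vim. Of listed markers, 3 of 18 luminal and 3 of 10 basal ones had a mean of at least 1 CPM in T23 cells alone, with Krt7 at 10.7 CPM ± 0.968 and Krt19 at 9.55 ± 0.767. Epithelial Epcam, Krt8 and Krt18, chosen after their values were seen, as were these keratins, were each under 1 CPM in all 18 libraries. Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183), which encodes a secreted collagen-binding glycoprotein, stood between 2586 and 3208 CPM in the 18 libraries. Since Sparc was lost in the fibroblasts and not in the T23 cells, this level does not show whether the fibroblasts lacked Sparc. Among neuroendocrine genes, Chga and Insm1 had 0 counts in all 18 libraries, which allows up to 0.112 to 0.186 CPM per library. Syp had 0 to 4 counts per library and the cytokine gene Il6 had 1 to 8, so neither passed the filter on low counts. Eno2 (37.6 to 49.6 CPM) and Ncam1 (81.5 to 146 CPM) were well measured. Of the 28 listed neuroendocrine markers only 8 had enough counts to be tested, so tests of that list cover only these 8.

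**Figure D2:**
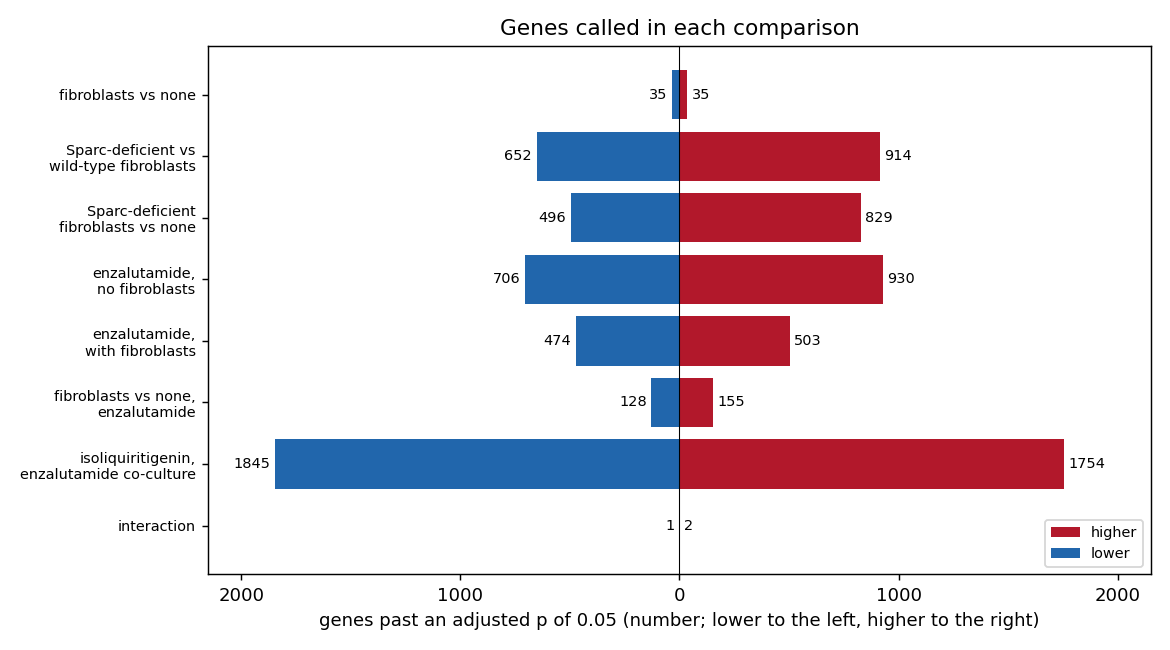
Number of genes past an adjusted p of 0.05 in each of the 8 tests, with lower genes to the left and higher genes to the right of 0. Isoliquiritigenin in the enzalutamide co-culture has the most called genes (1754 higher and 1845 lower) and the interaction the fewest (2 higher and 1 lower).

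Wild-type fibroblasts changed few genes of the T23 libraries, and the changes were small. The transcription factor genes Egr1 and Fos were lower in co-culture, Egr1 1.58-fold (log2 -0.66 ± 0.08, adjusted p 0.000276) and Fos 1.79-fold lower (adjusted p 0.0259). Mgp, which encodes an inhibitor of calcification, was 1.53-fold lower at 108 CPM ± 4.95 against 165 ± 10.6 (SD, n = 3; adjusted p 0.0042). Ranbp3l rose 3.78-fold from 3.48 CPM ± 2.56 to 13.0 ± 2.89 (adjusted p 0.0155), the matrix gene Fbln7 rose 1.79-fold (adjusted p 0.00304) and the retinal reductase gene Dhrs3 rose 1.64-fold (adjusted p 0.00304). Fndc1 (log2 0.70) and Ifi205 (0.60) were also higher, and Meox1 (-0.86), Adcyap1r1 (-0.69) and Ypel4 (-0.67) were lower.

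Of 13600 genes, 70 were called, 35 higher and 35 lower, 3 of them at least 2-fold. The TGF-beta response list fell as a group (adjusted p 1.32e-05), with 4 of 17 tested members lower and 1 higher, or 9 lower and 1 higher adjusted over the list alone. Its lower members included Ccn2 (log2 -0.40), Ccn1 (-0.32) and Lox (-0.34), genes of matricellular proteins and of a collagen crosslinking enzyme. In the IL-6 and STAT3 response list (adjusted p 0.000165) Fos was the 1 called member of 17, with 3 lower adjusted over the list alone. Both lists also passed with an estimated correlation (adjusted p = 0.0339 for each). The call of NRF2 targets (adjusted p 0.0165; 1 of 18 higher, Gsta4, or 3 adjusted over the list alone) was lost, with adjusted p = 0.509 with an estimated correlation. The hypoxia and glycolysis list (median -0.06, adjusted p 0.0468) had 0 of 22 members called by edgeR, over all genes or adjusted over the list alone, and its call was lost, with adjusted p = 0.897 with an estimated correlation and 0.0502 with the numbering series as a term. Sparc (log2 -0.06 ± 0.05, adjusted p 0.722), Ncam1 (-0.13 ± 0.07, 0.574), Hspa5 (0.14 ± 0.05, 0.276) and Eno2 (-0.03 ± 0.08, 0.936) did not pass. The count depended on single libraries and settings, at 14 without T23 alone replicate 1, 11 without its replicate 3, 11, 14 and 39 without wild-type co-culture replicates 1, 2 and 3, 157 without the library rich in ribosomal RNA, 336 with only these groups in the fit, 165 without a filter and 152 by DESeq2. Of the 15 named genes called, Egr1, Mgp, Fbln7 and Dhrs3 kept their calls without any 1 of the 6 libraries, and the other 11 lost them without at least 1 (adjusted p 0.0572 to 0.279 where lost), with each of the 6 libraries ending at least 1 call.

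Sparc-deficient fibroblasts, against wild-type fibroblasts, left T23 libraries with more transcripts of the IL-6 and STAT3 response and of the NF-kB target lists. The chemokine gene Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063) was 10-fold higher, at 10.6 CPM ± 2.06 against 1.06 ± 0.224 (SD, n = 3; log2 3.32 ± 0.23, adjusted p 1.45e-09). The alarmin gene Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718) was 4.71-fold higher (log2 2.23 ± 0.16, adjusted p 2.99e-09), Fos 3.59-fold (1.85 ± 0.16, 3.48e-08) and the neutrophil chemokine gene Cxcl1 2.58-fold (1.37 ± 0.12, 3.13e-08). Ncam1, a neural adhesion gene used as a neuroendocrine marker, was 1.18-fold higher (log2 0.23 ± 0.07, adjusted p 0.0363), a call lost without any 1 of wild-type replicates 1 and 2 or of the 3 Sparc-deficient replicates (adjusted p 0.0674 to 0.146) and with the replicate block (0.0534).

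In this comparison 1566 genes were called, 914 higher and 652 lower, 104 of them at least 2-fold. The other genes with the largest increases were the class I histocompatibility gene H2-Q7 (log2 1.35) and the transcription factor gene Cebpd (1.19). Those with the largest decreases were Sparcl1, a Sparc paralog (-1.33 ± 0.08, adjusted p 2.22e-10), Akr1c14 (-1.15), the collagen gene Col8a2 (-1.08), the Wnt agonist gene Rspo2 (-1.06) and the non-coding RNA Bc1 (-1.39 ± 0.41, adjusted p 0.029). The call of Bc1 was lost without any 1 of 4 libraries (wild-type replicates 2 and 3, Sparc-deficient replicates 2 and 3; adjusted p 0.0535 to 0.211) and by DESeq2 (0.0869). Sparc itself (log2 -0.02 ± 0.05, adjusted p 0.864), Hspa5 (-0.06 ± 0.05, 0.517) and Eno2 (0.07 ± 0.08, 0.646) did not pass.

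The IL-6 and STAT3 response list rose most clearly (adjusted p 4.03e-28; 8.25e-06 with an estimated correlation). Of its 17 tested members, 13 rose and 0 fell, or 14 and 0 adjusted over the list alone, among them the feedback inhibitor gene Socs3 (log2 0.90 ± 0.07) and the oncostatin M receptor gene Osmr (0.73 ± 0.06). Il6 itself was at 0.189 CPM ± 0.136 (SD, n = 3) against 0.104 ± 0.0533. In the hypoxia and glycolysis list (adjusted p 3.49e-20) 19 of 22 members rose, or 20 adjusted over the list alone, including the peptide hormone gene Adm (log2 0.96), the collagen hydroxylase gene P4ha2 (0.66) and the glucose transporter gene Slc2a1 (0.53). Inflammatory cytokines and NF-kB targets rose (adjusted p 4.29e-07; 5 of 13 higher and 1 lower, or 9 and 1 adjusted over the list alone), with Ptgs2 at log2 0.93 and Csf1 at 0.36. The TGF-beta response list rose (adjusted p 4.81e-06; 8 of 17 higher and 2 lower, or 9 and 2 adjusted over the list alone), with Ccn1 at 0.88, Ccn2 at 0.76 and Lox at 0.60. That list fell in the wild-type co-culture used as reference here, against T23 cells alone (adjusted p 1.32e-05). With Sparc-deficient fibroblasts against T23 cells alone it was not called (adjusted p 0.0889, 7 of 17 higher and 2 lower). Integrins and collagen receptors rose (adjusted p 0.000295; 2 of 15, Itga11 at 0.47 and Itga6 at 0.50, or 5 adjusted over the list alone, and 5 over all genes without the library rich in ribosomal RNA), as did luminal epithelial markers (adjusted p 0.00042; 3 of 5 over all genes and adjusted over the list alone, Krt7 at 0.92, Hoxb13 at 0.80 and Krt19 at 0.51). These 6 lists passed with an estimated correlation, hypoxia and glycolysis at 0.0333, NF-kB targets at 0.0213, TGF-beta response at 0.0247, integrins at 0.0333 and luminal markers at 0.0281. Without the library rich in ribosomal RNA, which is not part of this comparison, that adjusted p was 0.0515 for hypoxia and glycolysis, 0.0566 for integrins and 0.0864 for luminal markers, of which 7 rather than 5 members were then tested. The call of Hoxb13 was lost without any 1 of replicates 1 and 3 of both co-cultures (adjusted p 0.0679 to 0.0822), and that of Krt19 without any 1 of wild-type replicates 1 and 2 and Sparc-deficient replicates 2 and 3 (0.101 to 0.129).

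A further 5 lists were called in this comparison with the preset correlation only. Proliferation genes fell (adjusted p 3.54e-05; 7 of 25 lower, or 12 adjusted over the list alone), among them the replication helicase genes Mcm4 (log2 -0.27) and Mcm5 (-0.32) and the survivin gene Birc5 (-0.22), with adjusted p = 0.195 with an estimated correlation. Sterol biosynthesis genes rose (adjusted p 0.00268; 5 of 19 higher, or 7 adjusted over the list alone), with Cyp51 at 0.22 and Insig1 at 0.19, and adjusted p = 0.182 with an estimated correlation. Aryl hydrocarbon receptor targets (adjusted p 0.0132; 2 of 4 higher, Cyp1b1 at 0.63 and Tiparp at 0.45; adjusted over the list alone 2 higher and 1 lower) and androgen receptor targets (adjusted p 0.0132; 3 of 14 higher, Sgk1 at 0.59, Ndrg1 at 0.50 and Per1 at 0.40, and 1 lower; the same counts adjusted over the list alone) each had adjusted p = 0.0829 with an estimated correlation. Those 3 androgen receptor list members are also known to respond to glucocorticoids, hypoxia or the circadian clock. Basal epithelial markers (adjusted p 0.043; 1 of 5 higher, Trp63 at 1.30, also adjusted over the list alone) had adjusted p = 0.122 with an estimated correlation. Neuroendocrine markers, with 8 of 28 listed ones tested, were not called (adjusted p 0.875). Of their 8 tested members Ncam1 was higher and Cplx2 lower (log2 -0.42 ± 0.11, adjusted p 0.0131), and Stmn2 was also higher adjusted over the list alone (0.57 ± 0.20). Fewer genes were called without wild-type replicate 1 (994), wild-type replicate 2 (857) or Sparc-deficient replicate 2 (903). Birc5 and Insig1 lost their calls without any 1 of wild-type replicates 1 and 2 and Sparc-deficient replicates 2 and 3 (adjusted p 0.0537 to 0.168 and 0.0791 to 0.116), and Insig1 also without a filter (0.0845).

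**Figure D3:**
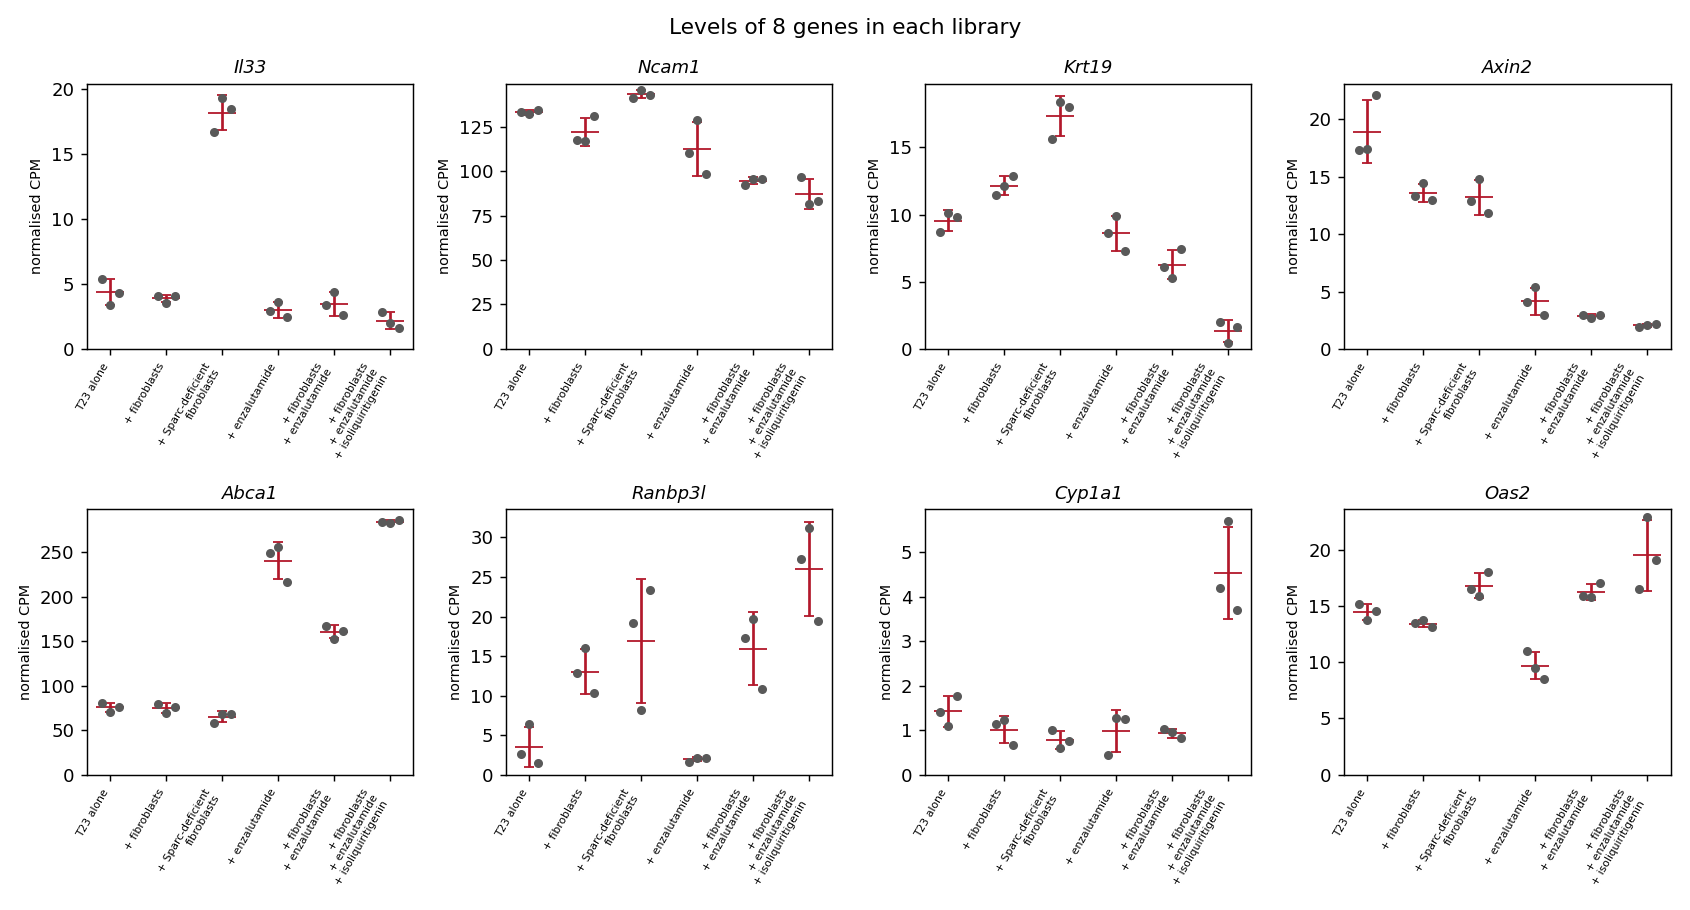
Normalised CPM of 8 genes in the 6 groups, with a point per library and bars for mean ± SD (n = 3). Il33 rises from 3.88 CPM with wild-type fibroblasts to 18.2 CPM with Sparc-deficient ones. Axin2 is at 17.3 to 22.1 CPM in the libraries of T23 cells alone and at a mean of 4.14 CPM with enzalutamide.

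With Sparc-deficient fibroblasts against T23 cells alone, Ppbp rose 10.4-fold (log2 3.38 ± 0.23, adjusted p 1.22e-09), Il33 4.14-fold (2.05 ± 0.16, 7.86e-09), H2-Q7 2.77-fold, the extracellular superoxide dismutase gene Sod3 2.68-fold and Ranbp3l 4.88-fold. The anion exchanger gene Slc26a7 fell 4.04-fold (log2 -2.01 ± 0.16, adjusted p 7.86e-09), Col8a2 2.97-fold, Kctd12 2.51-fold, Sparcl1 2.27-fold and Rspo2 2.18-fold. Sparc (log2 -0.08, adjusted p 0.351), Hspa5 (0.08, 0.359), Ncam1 (0.11, 0.421) and Eno2 (0.04, 0.835) did not pass.

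Called genes numbered 1325, 829 higher and 496 lower, 105 of them at least 2-fold. IL-6 and STAT3 response genes rose (adjusted p 8.21e-18; 11 of 17 higher, or 12 higher and 1 lower adjusted over the list alone), with Il4ra at log2 0.82, Osmr at 0.79 and Socs3 at 0.75. Luminal markers rose (adjusted p 1.2e-06; 2 of 5, Krt7 at 1.17 and Krt19 at 0.86, or 3 adjusted over the list alone). Both passed with an estimated correlation (adjusted p = 0.000117 and 0.00616). The other 6 calls did not. Hypoxia and glycolysis genes rose (adjusted p 4.64e-15; 17 of 22 higher over all genes and adjusted over the list alone, with Adm at 0.77, P4ha2 at 0.66 and the carbonic anhydrase gene Car9 at 1.18), with adjusted p = 0.0894 with an estimated correlation. Adjusted p = 0.0612 with an estimated correlation was found for NF-kB targets (preset 6.25e-05; 5 of 13 higher over all genes and adjusted over the list alone, with Cxcl1 at 1.11, Ptgs2 at 0.71 and Csf1 at 0.31). Integrins (preset 0.0015; 4 of 15 higher, with Itga6 at 0.66, Itga11 at 0.40 and Itga5 at 0.24; 5 higher and 1 lower adjusted over the list alone) had adjusted p = 0.0761 with an estimated correlation. Aryl hydrocarbon receptor targets (preset 0.0214; 2 of 4 higher, Cyp1b1 at 0.81 and Tiparp at 0.30; 2 higher and 1 lower adjusted over the list alone) had adjusted p = 0.121 with an estimated correlation. Sterol biosynthesis (preset 0.00841; 5 of 19 higher, with Lss at 0.25 and Sc5d at 0.22; 8 adjusted over the list alone) and proliferation (preset 6.25e-05; 6 of 25 lower over all genes and adjusted over the list alone, with Tyms at -0.34, Rrm2 at -0.22 and Ccna2 at -0.19) each had adjusted p = 0.203 with an estimated correlation. The call of Ccna2 was lost without T23 alone replicate 1 (adjusted p 0.0516) or Sparc-deficient replicates 2 (0.0518) or 3 (0.0639). Counts were 778, 743 and 861 without T23 alone replicates 1, 2 and 3, 794 and 870 without Sparc-deficient replicates 2 and 3, and 2188 with only these groups in the fit.

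Enzalutamide without fibroblasts lowered Axin2, Fmod, Nog, Hopx and Apcdd1 most among named genes, and raised NRF2 target genes. Axin2, a feedback inhibitor of Wnt signalling (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), fell 4.78-fold (log2 -2.26 ± 0.14, adjusted p 2.12e-10). It stood at 17.3 to 22.1 CPM in the 3 libraries of T23 cells alone and at 4.14 CPM ± 1.19 with enzalutamide (SD, n = 3). Apcdd1, another Wnt inhibitor gene, fell 2.40-fold (log2 -1.26 ± 0.09), the BMP antagonist gene Nog 2.65-fold, the matrix gene Fmod 3.21-fold and the homeobox gene Hopx 2.48-fold. Sparc fell 1.21-fold in 3 of 3 libraries, from 3197 CPM ± 9.24 to 2636 ± 40.4 (log2 -0.28 ± 0.05, adjusted p 0.000282). The cholesterol efflux gene Abca1 stood at 240 CPM ± 21 against 75.5 ± 5.15.

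Called genes numbered 1636, 930 higher and 706 lower, 113 of them at least 2-fold. Genes with the largest increases were RNAs that carry no poly(A) tail or a short one, and they rested on replicate 2, with 26.4% of its counts on CT010467.1. Rn7sk had a log2 fold change of 8.14 ± 1.60 with all libraries and 0.77 without that replicate (adjusted p 0.25), and CT010467.1 had 7.63 ± 1.35 and 0.86 (0.00131). The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 had 4.27 and 4.25 with all libraries, and 0.42 (0.0157) and 0.32 (0.0117) without that replicate. Without it the largest increases were in mt-Nd4 (log2 1.66 ± 0.27), Abca1 (1.63 ± 0.07, adjusted p 1.68e-15), mt-Cytb (1.61), mt-Co1 (1.61) and Sparcl1 (1.49 ± 0.07, adjusted p 3.77e-14). The largest decreases were then in Axin2 (-2.42), Fmod (-1.74), Nog (-1.42), Hopx (-1.29) and Dpt (-1.25). All 7 tested mitochondrially encoded messenger RNAs were higher, over all genes and adjusted over the list alone (adjusted p 2.25e-12; median 1.25, 0.87 without replicate 2; mt-Nd4 at 1.85, mt-Cytb at 1.81 and mt-Nd5 at 1.16), with adjusted p = 0.0622 with an estimated correlation. Mitochondrial genes, ribosomal RNAs included, took 2.74% of the counts in this group and 0.924% in T23 cells alone. The share was 4.06% in replicate 2, and 1.88% and 2.29% in replicates 1 and 3.

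NRF2 targets rose (adjusted p 5.44e-12; 0.0289 with an estimated correlation), with 12 of 18 members higher, or 13 adjusted over the list alone, among them Gsta4 (log2 0.81 ± 0.08), Gclc (0.49 ± 0.07) and Pgd (0.38 ± 0.05), enzymes of glutathione and NADPH metabolism. Fibroblast markers fell (adjusted p 7.73e-07; 0.0289 with an estimated correlation), with 10 of 27 lower and 2 higher, or 12 and 2 adjusted over the list alone, including Dpt (-1.25), Mfap5 (-0.91) and Mfap4 (-0.83). Sterol biosynthesis genes rose (adjusted p 7.6e-07; 11 of 19 higher, or 12 adjusted over the list alone), with Msmo1 at 0.33 and Insig1 at 0.30. That list had adjusted p = 0.0622 with an estimated correlation. Interferon response genes fell (adjusted p 0.00026; 7 of 26 lower, 4 without the library rich in ribosomal RNA, or 10 lower and 2 higher adjusted over the list alone), with Oas1a at -0.69, Oas2 at -0.58 and Xaf1 at -0.34. Hypoxia and glycolysis genes fell too (adjusted p 1.38e-05; 9 of 22 lower, or 12 adjusted over the list alone), with Eno1 at -0.53, Ldha at -0.32 and Adm at -0.35. Both had adjusted p = 0.429 with an estimated correlation. The TGF-beta response list fell (adjusted p 0.0113; 6 of 17 lower and 2 higher, or 7 and 2 adjusted over the list alone), with Ccn1 at -0.59 and Ccn2 at -0.42, and had adjusted p = 0.225 with an estimated correlation. Androgen receptor targets were not called (adjusted p 0.983; 1 of 14 higher and 2 lower). Neuroendocrine markers were not called either (adjusted p 0.334), with Syt1 higher (log2 0.56) and Stmn2 (-0.86), Uchl1 (-0.40) and Ncam1 (-0.25 ± 0.07, adjusted p 0.0257) lower of 8 tested. Without replicate 2 the calls of Syt1 (0.50, adjusted p 0.108) and Uchl1 (-0.25, 0.0899) were lost, and those of Ncam1 (-0.35, 0.000618) and Stmn2 (-0.75, 0.0276) were not.

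Hspa5 (log2 0.11 ± 0.05, adjusted p 0.155) and Eno2 (-0.15 ± 0.09, 0.287) did not pass. The call of Ncam1 was lost without any 1 of the 3 T23 alone replicates or of enzalutamide replicates 1 and 3 (adjusted p 0.061 to 0.125). Adm lost its call without T23 alone replicate 1 (0.0522) or 3 (0.0544), and Xaf1 without T23 alone replicate 2 (0.0548) or enzalutamide replicate 3 (0.0648). With only these groups in the fit, the calls of Ncam1 (0.114), Adm (0.056) and the 4 non-polyadenylated RNAs (0.0523 to 0.0727) were lost. The number of calls was 951, 1024 and 901 without T23 alone replicates 1, 2 and 3, and 740 with only these groups in the fit. Without enzalutamide replicate 2 there were 1281 calls, 673 higher and 608 lower, and 1076 of these were among the 1636 with all libraries.

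In fibroblast co-culture, enzalutamide lowered Axin2 by a like factor and raised Abca1 and Sparcl1. Axin2 fell 4.73-fold (log2 -2.24 ± 0.15, adjusted p 9.92e-10), the Wnt ligand gene Wnt7b 2.2-fold (-1.13 ± 0.10, 8.56e-08), the imprinted RNA H19 2.43-fold, the growth cone gene Gap43 2.39-fold and Ankrd37 2.04-fold. Sparcl1 (ENSMUSG00000029309, chromosome 5, 104079111 to 104113733) rose 2.23-fold and Abca1 (ENSMUSG00000015243, chromosome 4, 53030787 to 53159895) 2.15-fold (adjusted p 5.39e-10 for each). Mitochondrial mt-Co1 rose 2.98-fold, mt-Nd4 2.95-fold and mt-Cytb 2.82-fold, in libraries with 2.32% of counts on mitochondrial genes against 1.02%. With enzalutamide that share was 1.55% in replicate 1, of the first numbering series, and 2.71% and 2.70% in replicates 2 and 3, of the second. In wild-type co-culture it was 1.34%, 0.857% and 0.853% in replicates 1, 2 and 3. Ncam1 fell 1.29-fold in 3 of 3 libraries (log2 -0.37 ± 0.07, adjusted p 0.00213), and Sparc was at -0.17 ± 0.05 (0.0234).

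Called genes numbered 977, 503 higher and 474 lower, 79 of them at least 2-fold. Of the genes called with and without fibroblasts, 593 went in the same direction and 3 in opposite directions, where 59 and 58.5 are expected from the sizes of the lists, and log2 fold changes correlated across genes at Pearson r 0.405 and Spearman rho 0.516 (disjoint libraries; genes are not independent replicates). Hypoxia and glycolysis genes fell (adjusted p 7.83e-23; 18 of 22 lower, or 20 adjusted over the list alone), with Bnip3 at log2 -0.82, Pgk1 at -0.56 and Ldha at -0.52. Mitochondrially encoded transcripts rose (adjusted p 1.09e-12; 7 of 7 over all genes and adjusted over the list alone; median 1.11, with mt-Nd5 at 1.11), as did sterol biosynthesis genes (adjusted p 2.71e-06; 7 of 19, or 10 adjusted over the list alone, with Hmgcs1 at 0.40 and Insig1 at 0.38). These 3 lists each had adjusted p = 0.0885 with an estimated correlation. NRF2 targets rose (adjusted p 2.83e-06; 5 of 18, or 10 adjusted over the list alone, with Gsta4 at 0.71, Fth1 at 0.37 and Nqo1 at 0.34), with adjusted p = 0.112 with an estimated correlation. Interferon response genes rose (adjusted p 4.98e-05; 7 of 26, or 10 adjusted over the list alone, with Ifit3 at 0.57, Oasl2 at 0.45 and Stat2 at 0.38), with adjusted p = 0.261 with an estimated correlation. Fibroblast markers fell (adjusted p 0.00635; 8 of 27 lower and 2 higher, or 10 and 3 adjusted over the list alone, with Dpt at -0.84, Mfap5 at -0.58 and Fbln2 at -0.49), with adjusted p = 0.157 with an estimated correlation. Hspa5 (log2 -0.07, adjusted p 0.454) and Eno2 (-0.07, 0.71) did not pass, nor did neuroendocrine markers (0.189) or androgen receptor targets (0.127). With the numbering series as a term 214 genes were called, and Ncam1 (-0.40, adjusted p 0.0596), Hmgcs1, Pgk1, Stat2, Ifit3, Oasl2, Ankrd37, Fth1, Nqo1, mt-Nd5, mt-Nd4, mt-Cytb and mt-Co1 were not called (0.0591 to 0.408), mt-Co1 at log2 0.76, mt-Nd4 at 0.83, mt-Cytb at 0.77 and mt-Nd5 at 0.68. With that term the contrast rests on enzalutamide co-culture replicate 1 alone, the only 1 of its group in the first series. A call lost there does not show that the series accounts for the change. Counts were 637 without wild-type co-culture replicate 3 and 550 without enzalutamide co-culture replicate 2. The call of Sparc was lost without any 1 of wild-type replicates 1, 2 and 3 or enzalutamide co-culture replicate 1 (adjusted p 0.0636 to 0.11). That of Nqo1 was lost without wild-type replicate 3 (0.0758).

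Under enzalutamide, libraries with fibroblasts had higher Ranbp3l, Sod3, Acpp and Fgl2 than those without. Ranbp3l was 8.22-fold higher with fibroblasts (ENSMUSG00000048424, chromosome 15, 8967949 to 9067335; log2 3.04 ± 0.42, adjusted p 0.00027), Sod3 2.05-fold, the acid phosphatase gene Acpp 1.85-fold, Fgl2 1.80-fold and the mitochondrial transfer RNA mt-Tc 1.74-fold. Interferon response genes rose (adjusted p 5.63e-28; 12 of 26 higher, or 17 adjusted over the list alone), with Oas2 at log2 0.74 ± 0.11, Ifit1 at 0.55 ± 0.08 and Rsad2 at 0.50 ± 0.08. That list passed with an estimated correlation (adjusted p = 0.0422), and had 0.0624 without the library rich in ribosomal RNA. Hypoxia and glycolysis genes fell (adjusted p 7.48e-16; 7 of 22 lower, or 16 adjusted over the list alone), with Ero1l at -0.84, Egln3 at -0.79 and Bnip3 at -0.73, and adjusted p = 0.198 with an estimated correlation. The TGF-beta response list fell (adjusted p 0.0141; 5 of 17 lower and 1 higher, or 9 and 2 adjusted over the list alone), with Ltbp2 at -0.50, Smad7 at -0.44 and Ccn2 at -0.32, and adjusted p = 0.223 with an estimated correlation.

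Of 283 called genes, 155 were higher and 128 lower, 37 of them at least 2-fold. Of the genes called for fibroblasts with and without enzalutamide, 34 went in the same direction and 0 in opposite directions (0.728 expected for each; Fisher's exact p 5.39e-10, across genes). Genes are not independent replicates, so that p does not measure replication across libraries. Without enzalutamide replicate 2, 63 went in the same direction and 0 in opposite directions (2.21 expected for each). Whether both co-cultures held the same fibroblasts is open. The largest decreases, in n-R5-8s1 (log2 -9.67), Rn7sk (-9.14), CT010467.1 (-8.03), Mir6236 (-5.57) and Bc1 (-2.06), were smaller without enzalutamide replicate 2. Of the 5, only Mir6236 then lost its call (log2 -0.26, adjusted p 0.569), while n-R5-8s1, Rn7sk (-1.77, 0.0271), CT010467.1 (-1.27, 8.77e-05) and Bc1 (-1.45, 0.0159) stayed called. The naming rule then picked CT010467.1 and Bc1 with Snrpf (-0.97), Dock8 (-0.93) and Arrdc4 (-0.76), while Scn7a (0.84) joined Ranbp3l (3.07), Sod3 (1.03), Acpp (0.95) and Fgl2 (0.87) among the largest increases. Sparc (log2 0.05, adjusted p 0.693), Hspa5 (-0.04, 0.759), Eno2 (0.05, 0.864) and Ncam1 (-0.24 ± 0.07, 0.0872) did not pass. With the numbering series as a term 11 genes were called. Of the genes named in this comparison Sod3, mt-Tc, Smad7, Ltbp2, Ccn2, Ifit1, Oas2, Bnip3, Ero1l, Egln3 and the 5 with the largest decreases were then not called (adjusted p 0.0785 to 0.493). With that term the contrast rests on enzalutamide co-culture replicate 1 alone, and these genes kept their direction. Bnip3 (-0.72), Ero1l (-0.83), Egln3 (-0.90), Ltbp2 (-0.54), Smad7 (-0.58) and Oas2 (0.71) were about as large or larger. Sod3 (0.70), mt-Tc (0.75), Ifit1 (0.41), Ccn2 (-0.24) and the 5 with the largest decreases were smaller. Without enzalutamide co-culture replicate 2 there were 83 calls, and those of Bc1, Ccn2, Egln3, Ltbp2, Mir6236, Rn7sk, Smad7 and mt-Tc were lost (0.0562 to 0.236). Without enzalutamide replicate 1 there were 148, and those of Ccn2, Egln3, Ltbp2, Smad7 and mt-Tc were lost (0.0571 to 0.133). The call of mt-Tc was also lost without enzalutamide replicate 2 (0.0534) or co-culture replicate 1 (0.0633), Ltbp2 without enzalutamide replicate 3 (0.0776) or co-culture replicate 1 (0.0836), Smad7 without co-culture replicate 1 (0.0755) and Ccn2 without co-culture replicate 3 (0.0792). With only these groups in the fit 56 genes were called and the calls of Fgl2 (0.089), Ccn2, Ltbp2, Smad7, mt-Tc and the 5 genes with the largest decreases were lost (0.089 to 0.167), and without a filter 541 genes were called.

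Isoliquiritigenin, added to enzalutamide in co-culture, changed more genes than any other treatment compared here. The keratin genes Krt19 and Krt7 fell, Krt19 by 4.52-fold (log2 -2.18 ± 0.24, adjusted p 3.02e-07) and Krt7 (ENSMUSG00000023039, chromosome 15, 101411043 to 101430313) by 3.49-fold (-1.80 ± 0.12, 2.18e-10), along with the growth factor gene Tgfa (3.41-fold), the calcium pump gene Atp2b4 (3.27-fold), the cornified envelope gene Sprr1a (3.25-fold) and the HIF hydroxylase gene Egln3 (3.21-fold). The matrix gene Smoc2 rose 4.03-fold (2.01 ± 0.16, 2.78e-09), the histone gene Hist1h1c 2.91-fold, the thyroid hormone receptor gene Thrb 2.78-fold, Igf1 2.72-fold and the autotaxin gene Enpp2 2.67-fold.

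Called genes numbered 3599, 1754 higher and 1845 lower, 278 of them at least 2-fold. Hypoxia and glycolysis genes fell (adjusted p 3.17e-24), with 21 of 22 lower over all genes and adjusted over the list alone, including Pgk1 (log2 -0.92) and Ndrg1 (-0.78). NRF2 targets rose (adjusted p 2.44e-09; 9 of 18, or 10 adjusted over the list alone), with the quinone reductase gene Nqo1 2.23-fold higher (1.16 ± 0.08, adjusted p 3.06e-10), Gsta4 at 0.84 and Gclc at 0.67. Sterol biosynthesis genes rose (adjusted p 2.44e-09; 12 of 19, or 17 adjusted over the list alone), with Mvd at 0.68, Insig1 at 0.59 and Lss at 0.40. Luminal markers fell (adjusted p 0.000726; Krt7 and Krt19, 2 of 5, over all genes and adjusted over the list alone). These 4 lists each had adjusted p = 0.0345 with an estimated correlation. NF-kB targets fell (adjusted p 0.000263; 0.049 with an estimated correlation), with 10 of 13 lower and 2 higher over all genes and adjusted over the list alone, including Tnfaip3 (-0.91), Ccl2 (-0.57) and Vcam1 (-0.32). Without the library rich in ribosomal RNA, which is not part of this comparison, that value was 0.0533 for NF-kB targets and 0.0533 for luminal markers.

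The remaining 8 lists called with isoliquiritigenin were lost with an estimated correlation. Proliferation genes fell (adjusted p 9.56e-09; 17 of 25, or 19 adjusted over the list alone), with Bub1b at log2 -0.50, Ccnb2 at -0.50 and Top2a at -0.46, and fibroblast markers fell (adjusted p 0.00262; 13 of 27 lower and 4 higher, or 17 and 5 adjusted over the list alone), with Dpt at -1.28, Dcn at -0.84 and Thy1 at -0.74. Both had adjusted p = 0.0747 with an estimated correlation. The list of integrins and collagen receptors fell (adjusted p 0.00238), with 6 of 15 lower over all genes and adjusted over the list alone. They included Stab1 (-1.99), which is not an integrin, Itga6 (-0.81) and Itga3 (-0.38). Neuronal stem and plasticity factors fell too (adjusted p 0.0204), with 9 of 15 lower and 2 higher, or 9 and 4 adjusted over the list alone. Among them Mycn was at -1.09, Jag1 at -0.92 and Hes1 at -0.64. Both lists had adjusted p = 0.0547 with an estimated correlation. Androgen receptor targets fell (adjusted p 0.0335; 4 of 14 lower and 2 higher, or 5 and 2 adjusted over the list alone, with Acpp at -1.33, Ndrg1 at -0.78 and Fkbp5 at -0.45), with adjusted p = 0.118 with an estimated correlation. Interferon response genes rose (adjusted p 3.37e-05; 16 of 26 higher and 3 lower, or 19 and 3 adjusted over the list alone, with Ifit1 at 0.67, Gbp3 at 0.48 and Stat2 at 0.39), with adjusted p = 0.273 with an estimated correlation. Aryl hydrocarbon receptor targets rose (adjusted p 0.0405; 2 of 4 over all genes and adjusted over the list alone, Cyp1a1 at 2.27 ± 0.28 and Cyp1b1 at 0.42), with adjusted p = 0.124 with an estimated correlation and 0.0599 with the numbering series as a term. Mitochondrially encoded transcripts rose (adjusted p 0.0249; 4 of 7, or 5 adjusted over the list alone, with mt-Nd2 at 0.66, mt-Nd5 at 0.62 and mt-Nd6 at 0.57), in libraries with 3.42% of counts on mitochondrial genes against 2.32%. Their adjusted p = 0.542 with an estimated correlation and 0.166 with the numbering series as a term. The calls of mt-Nd2, mt-Nd5 and mt-Nd6 were lost without enzalutamide co-culture replicate 1 (adjusted p 0.0942, 0.111 and 0.205) and with the numbering series as a term (0.0961, 0.113 and 0.207). With that term the contrast rests on enzalutamide co-culture replicates 2 and 3, so both settings make nearly the same check (mt-Nd2 at log2 0.478 and 0.477). The call of mt-Nd6 was also lost without any 1 of the 3 isoliquiritigenin replicates (0.053 to 0.102) and by DESeq2 (0.117), and that of mt-Nd5 without isoliquiritigenin replicate 2 (0.055) and by DESeq2 (0.0521). Neuroendocrine markers were not called (adjusted p 0.683; 1 of 8 higher, Uchl1 at 0.36), and Sparc (log2 0.03, adjusted p 0.691), Hspa5 (-0.12, 0.0719), Eno2 (0.13, 0.291) and Ncam1 (-0.11, 0.27) did not pass.

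**Figure D4:**
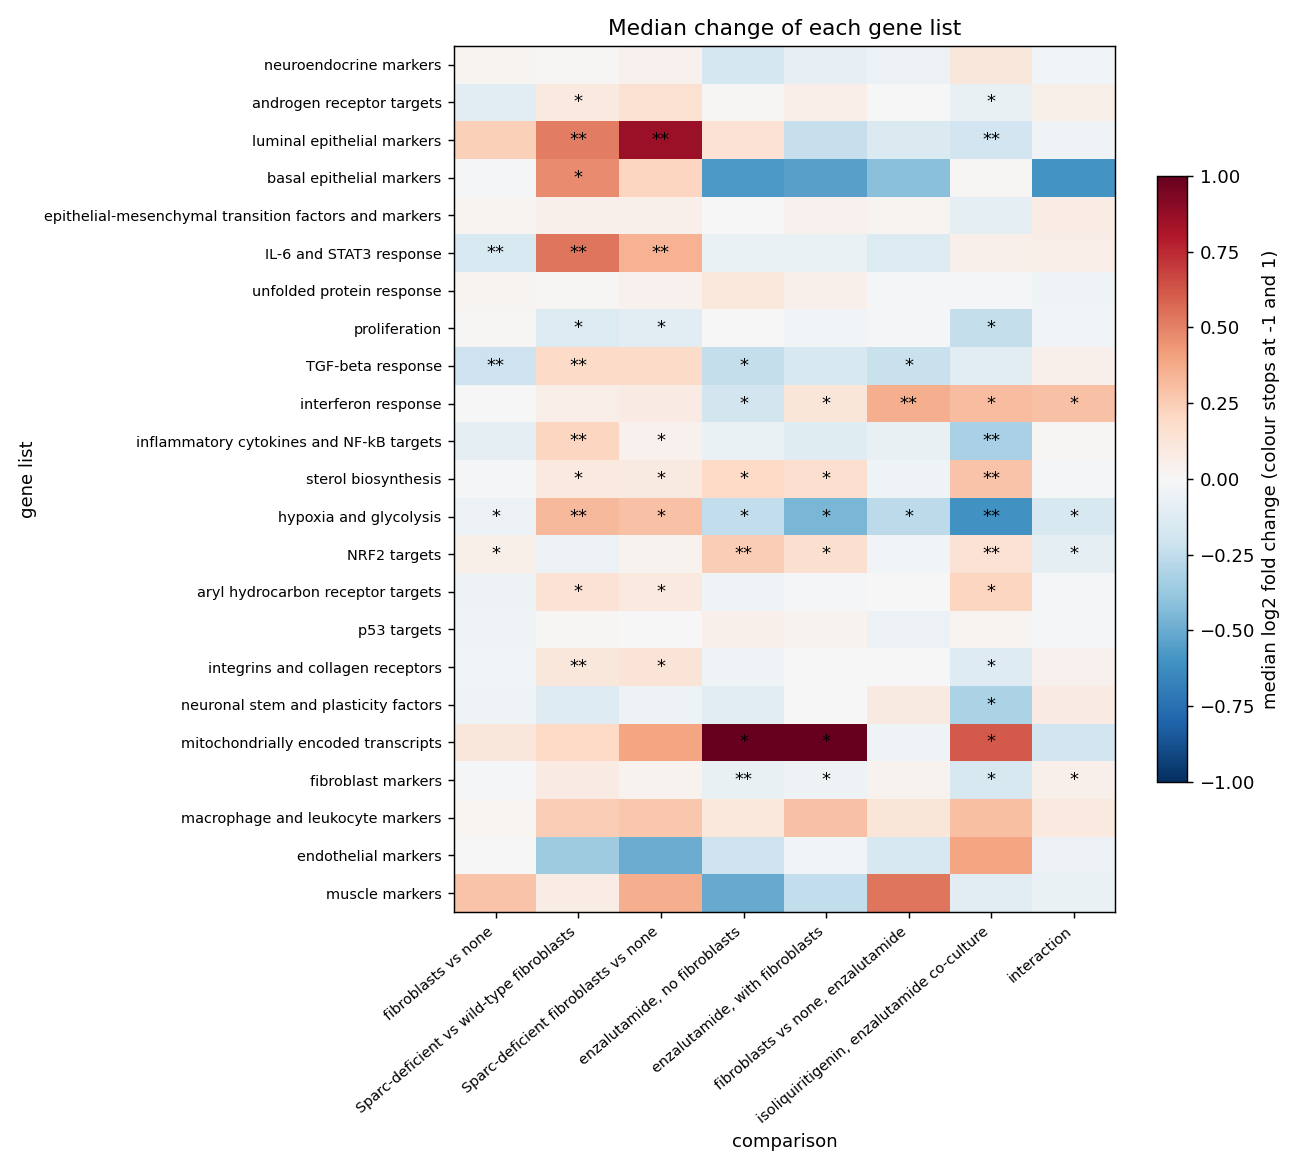
Median log2 fold change of the tested members of 23 gene lists (vertical axis) in 8 tests (horizontal axis), with colour limited to -1 and 1, * for a camera adjusted p under 0.05 and ** where it also holds with an estimated correlation. Hypoxia and glycolysis is called in all 8 tests, with medians from -0.61 to 0.32, but in 2 of the 8 with an estimated correlation. Neuroendocrine markers, with 8 of 28 listed ones tested, are called in 0, with a lowest adjusted p of 0.189.

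The enzalutamide response differed with and without fibroblasts in 3 genes at the edge of the threshold. Oas2, an antiviral gene, was at 14.5 CPM ± 0.727 in T23 cells alone and 9.68 ± 1.22 with enzalutamide, against 13.4 ± 0.309 in co-culture and 16.3 ± 0.709 in co-culture with enzalutamide (SD, n = 3). The glutathione-degrading enzyme gene Chac1 was at 12.7 CPM ± 0.621 and 10.3 ± 1.05 without fibroblasts, and at 8.39 ± 0.497 and 11.9 ± 0.613 with them. Abca1 stood at 75.5 CPM ± 5.15 and 240 ± 21 without fibroblasts, and at 74.6 ± 5.46 and 160 ± 7.09 with them. The differences were log2 0.85 ± 0.15 for Oas2, 0.78 ± 0.14 for Chac1 and -0.56 ± 0.10 for Abca1 (adjusted p 0.0496 for each). All 3 calls were lost with RLE size factors (0.0514), with the replicate block (0.096), with only the 4 groups in the fit (0.0612 to 0.0731), with the numbering series as a term (0.49 to 0.967) and without any 1 of the 3 replicates of T23 alone, the 3 of wild-type co-culture, enzalutamide replicate 2 and enzalutamide co-culture replicates 2 and 3 (0.0506 to 0.268). Abca1 was also lost without enzalutamide replicate 1 (0.0689) and Oas2 without its replicate 3 (0.0836). With the numbering term, where enzalutamide co-culture rests on replicate 1 alone, the differences were log2 0.82 for Oas2, 0.85 for Chac1 and -0.51 for Abca1. The number of calls was 0 without any 1 of those 9 libraries, 7 and 10 without enzalutamide replicates 1 and 3, 12 without enzalutamide co-culture replicate 1, 0 under each of these other settings, 99 without a filter and 3 by DESeq2, and 755 genes had an unadjusted p under 0.05. As lists, interferon response was higher (adjusted p 2.82e-25; median 0.29; 1 of 26 members called, 13 adjusted over the list alone) and hypoxia and glycolysis (5.38e-08; median -0.16) and NRF2 targets (0.00127; median -0.10) lower, while fibroblast markers were higher (0.0046; median 0.05). In the latter 3 lists, edgeR called 0 members over all genes or adjusted over the list alone. They had adjusted p = 0.252 with an estimated correlation each, interferon response had adjusted p = 0.0613 with an estimated correlation, and fibroblast markers had 0.0932 with the numbering series as a term. Sparc (log2 0.11, adjusted p 0.926), Hspa5 (-0.18, 0.762), Eno2 (0.08, 0.975) and Ncam1 (-0.12, 0.949) did not pass.

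Responses to Sparc-deficient fibroblasts and to enzalutamide in co-culture, both measured against wild-type co-culture, shared 108 genes in the same direction, 85 higher and 23 lower, where list sizes alone give 33.8 and 22.7. A larger set of 206 shared genes went in opposite directions, where 56.0 are expected. Across genes, Pearson r was 0.0886 and Spearman rho 0.0544, below the r of 0.495 that the shared control alone gave in simulated data, and over the genes above 10 CPM the sign turned, with Pearson r -0.0873 against a simulated 0.509. Over all genes the covariance was 0.0101 under the simulated one (0.00773 against 0.0178). The simulated groups had no changed genes, and real changes that are unrelated between both responses also lower r. A lower r therefore does not tell opposite responses from unrelated ones. The simulated spread came from all 18 libraries, enzalutamide replicate 2 included, which is outside both comparisons. The simulated covariance may thus be too large, and the difference does not decide whether the responses are opposite. Ncam1 (0.23 and -0.37) is among the genes called in both with opposite signs. Against disjoint controls, 102 genes were called in the same direction (96.3 expected) and 281 in opposite directions (92.0 expected) for Sparc deficiency and enzalutamide without fibroblasts (Pearson r -0.128). For Sparc-deficient fibroblasts against T23 alone and enzalutamide in co-culture there were 118 in the same direction (48.0 expected) and 171 in opposite directions (47.2 expected; Pearson r 0.0213). The shared count was 27 with the numbering series as a term, 165 without the library rich in ribosomal RNA, and 61 without wild-type co-culture replicate 2.

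Among lists called in none of the 8 tests, epithelial-mesenchymal transition factors and markers had a lowest adjusted p of 0.426, the unfolded protein response 0.109, p53 targets 0.169, macrophage and leukocyte markers 0.0606, endothelial markers 0.079 and muscle markers 0.317. Of 6 sex-linked transcripts none had enough counts to be tested.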

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

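The tests on non-polyadenylated RNAs and on mitochondrially encoded messenger RNAs were chosen only after the result was seen. A difference between the enzalutamide effect with and without fibroblasts, tested as an interaction, picked out the genes and lists that follow. The effect with fibroblasts minus that without was log2 0.85 for Oas2, 0.78 for Chac1 and -0.56 for Abca1 (adjusted p 0.0496 each). The list medians were 0.29 for interferon response, -0.16 for hypoxia and glycolysis, -0.10 for NRF2 targets and 0.05 for fibroblast markers, and none of these 4 lists passed with an estimated correlation. Of 100 seeded regroupings of the 12 libraries, the real one included, 10 gave at least 3 calls, and the highest other gave 989. These regroupings mix the effects of enzalutamide and of fibroblasts into the contrast, and no other structure of the samples was tested. The regroupings therefore do not test for chance in the interaction alone. Groups of 3 libraries are too small for a test of single outlying values within a group, which was not run.

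For the 7 comparisons of 3 libraries against 3, the 10 splits of each cannot give a share under 0.05. In each, only 1 split, the real one, gave as many calls. Real counts were 70 for wild-type fibroblasts, 1566 and 1325 for Sparc-deficient fibroblasts against wild-type fibroblasts and against T23 alone, 1636 and 977 for enzalutamide without and with fibroblasts, and 3599 for isoliquiritigenin, and the highest other split gave 0 in each of these 6. For fibroblasts under enzalutamide the real count was 283 and the highest other 108, in the split that sets enzalutamide replicates 1 and 3 with co-culture replicate 1 against enzalutamide replicate 2 with co-culture replicates 2 and 3.

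RNAs without a poly(A) tail, or with a short one, led the genes higher under enzalutamide without fibroblasts. Without replicate 2 the median log2 fold change of the 7 RNAs was 0.42, against 4.25 to 8.14 for single RNAs with all libraries, as 1 library with inefficient poly(A) selection would give. An effect of enzalutamide on these RNAs stays open, since 3 of the 7 (CT010467.1, mt-Rnr1 and mt-Rnr2) were still called higher without that library.

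Mitochondrially encoded messenger RNAs were higher under enzalutamide in co-culture, with a median of 1.11, and the list had adjusted p = 0.0885 with an estimated correlation. For more non-polyadenylated RNA in the libraries, the median of those RNAs was -0.44 there, with edgeR adjusted p of 0.861 to 0.994. The spread in that fit includes enzalutamide replicate 2, so this median alone does not exclude a rise. CT010467.1 took 0.0661%, 0.0461% and 0.0391% of the counts in enzalutamide co-culture replicates 1, 2 and 3. In wild-type co-culture its share was 0.0657%, 0.0663% and 0.0750%. These shares argue against more of that RNA. The numbering series cannot be told apart from the treatment for these genes. With the series as a term the median was 0.68 and the list passed with the preset correlation (adjusted p 0.000113), which met the bound set for reading it against the series, but that reading was withdrawn once the values were seen, because 0 of 7 members were called by edgeR and the fit rests on enzalutamide co-culture replicate 1 alone. Enzalutamide is a candidate explanation, since 7 of 7 members were called higher without fibroblasts and without replicate 2, in libraries of a single series. In that comparison, though, the non-polyadenylated RNAs had a median of 0.42, with 3 of 7 called higher. More such RNA therefore stays open without fibroblasts.

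Many genes differed between co-cultures with Sparc-deficient and wild-type fibroblasts. RNA of the fibroblasts themselves stays open. Of 32875 genes with 0 counts in every T23 alone library, 0 reached 1 CPM in every Sparc-deficient co-culture library. The bound set beforehand would have read this against carry-over, but that bound was wrong, because 25 of 30 fibroblast markers stand at 10 CPM or more in T23 cells alone, so fibroblasts of a like profile would leave those genes silent. Sparc ranged from 2977 to 3101 CPM with Sparc-deficient and from 3049 to 3092 CPM with wild-type fibroblasts. A large share of RNA from fibroblasts without Sparc transcripts would have lowered it. The labels do not say whether the deficiency removes the transcript, and a small share would not show, so Sparc does not decide carry-over.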

How the results depend on the processing

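The fits without enzalutamide replicate 2 for every comparison, with the numbering series as a term and on protein-coding nuclear genes were chosen only after the result was seen. Fibroblasts against T23 alone gave 165 calls without a filter, 152 by DESeq2, 336 with only the compared groups in the fit and 11 to 157 without 1 library. Sparc deficiency gave 857 to 2085 without 1 library. Sparc-deficient fibroblasts against T23 alone gave 2188 with only the compared groups and 743 to 1724 without 1 library. Enzalutamide without fibroblasts gave 740 with only the compared groups and 901 to 1710 without 1 library. In co-culture it gave 214 with the numbering term and 550 to 1423 without 1 library. Fibroblasts under enzalutamide gave 541 without a filter, 56 with only the compared groups, 11 with the numbering term and 83 to 419 without 1 library. The interaction gave 0 with RLE, with the replicate block, with only the compared groups and with the numbering term, 99 without a filter and 0 to 12 without 1 library. The overlap was 27 with the numbering term and 61 to 165 without 1 library. Upper ends of 157, 2085, 1724, 1423 and 165 are from fits without enzalutamide replicate 2, which is outside those comparisons. With the numbering term, comparisons of the enzalutamide co-culture with first-series groups, the interaction and the overlap rest on its replicate 1 alone.

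Signs turned in 8 gene values, none called. For Eno2 without 1 library the values were -0.0842 to 0.00732 for fibroblasts against T23 alone, -0.0101 to 0.0814 for Sparc-deficient fibroblasts against T23 alone and -0.0140 to 0.162 for fibroblasts under enzalutamide. For Sparc they were -0.00761 to 0.0490 without 1 library and -0.00807 with the numbering term for isoliquiritigenin, and -0.0276 with that term for fibroblasts under enzalutamide, where Hspa5 was 0.0103. Of the values of named genes, 3001 were the same in call and direction, 211 weaker and 6 stronger. Without 1 library, 38 gene results lost the call. The 234 gene results with a test include genes that were not called and so had no call to lose. Lists were run only with RLE, the replicate block, the numbering term, an estimated correlation and without enzalutamide replicate 2. Of list results 238 were the same and 42 weaker, 38 of these with an estimated correlation and 4 with the numbering term. Without enzalutamide replicate 2 the called members went from 7 to 4 for interferon response and 9 to 12 for hypoxia and glycolysis under enzalutamide without fibroblasts. They went from 5 to 8 for NRF2 targets under enzalutamide in co-culture, from 12 to 15 for sterol biosynthesis under isoliquiritigenin and from 4 to 7 for TGF-beta response with wild-type fibroblasts. For Sparc deficiency they went from 2 to 5 for integrins and 7 to 10 for proliferation, and for Sparc-deficient fibroblasts against T23 alone from 5 to 8 for sterol biosynthesis. Other called lists moved by 2 or fewer in a direction. The cause was not tested.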

Other observations

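The Wnt, LXR and isoliquiritigenin tests were written before their results were seen, but after the genes that prompted them. Abca1 was higher under enzalutamide with fibroblasts (log2 1.11) and without (1.63, replicate 2 left out), and 6 of 11 further tested targets of the oxysterol receptor LXR were called higher in both comparisons, while Srebf1, Apoe, Nr1h3, Pltp and Smpdl3a were called in neither. Values follow without fibroblasts, replicate 2 left out, and then with them. Abcg1 was at log2 1.74 and 1.51, Mylip at 0.68 and 0.50, Fasn at 0.49 and 0.28, Scd1 at 0.43 and 0.25, Scd2 at 0.40 and 0.24 and Lpcat3 at 0.32 and 0.26. The 11 tested targets other than Abca1 had a camera p of 6.79e-07 in the weaker of both comparisons, and 9.30e-05 and 0.000218 with an estimated correlation in the respective comparisons. Higher LXR activity is a hypothesis for this set, consistent with these values, and blocking LXR in enzalutamide-treated T23 cells would test it.

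Axin2, Apcdd1, Nog and Wnt7b were lower under enzalutamide in at least 1 of both settings, which may reflect lower Wnt signalling. The other 10 tested targets do not decide it, with a camera p of 0.326 without fibroblasts (replicate 2 left out) and 0.0496, lower, in co-culture, where it was 0.0992 with an estimated correlation. Without fibroblasts Myc was higher (0.32) and Lgr5 lower (-1.12). A Wnt reporter in treated cells would test it.

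Sparc deficiency and isoliquiritigenin moved some genes in opposite directions, such as Krt7. Of genes called in both, 516 were opposite and 206 in the same direction, where 208 and 206 are expected. Across genes Pearson r was -0.192, short of the bound of -0.2 set beforehand for it. Over the genes above 10 CPM, for which no bound was set, it was -0.209, and -0.205 without enzalutamide replicate 2. Opposite responses stay open. Adding isoliquiritigenin to Sparc-deficient co-culture would test it.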
